A study of Drosophila melanogaster with 12 samples.

How the data were processed

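Total RNA of adult Drosophila melanogaster had been measured on 12 oligonucleotide arrays, 3 for each combination of genotype and diet. The flies were starved overnight and then fed sucrose or sucrose with 0.3% phenobarbital, per the labels. The sample titles carry the short names CS and E25. CS was read as Canton S and E25, by elimination, as the DHR96 mutant, since the series names only these strains. The labels give neither the sex of the flies nor whether the arrays of a group came from separate cultures. The deposited values are normalized expression intensities per probe set, made by the submitters with GCRMA, which corrects background, normalizes arrays and summarises the probes of a set, per the submitters' processing notes. The version of GCRMA is not given in the sources used here. The intensities were read as being on a linear scale from their range, since the lowest value of an array was 2.46 to 2.49 and the largest 48233 to 52446, and log2 of the deposited intensity was taken here. No array was rescaled further and no value was missing.

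All 18769 probe sets were tested. Gene names came from the platform table, with 13647 probe sets naming 1 gene, 402 naming several and 4720 naming none, and 11982 distinct genes in all. Symbols were checked through 13544 Entrez identifiers against the Drosophila gene table of Release 6 plus ISO1 MT, which changed 0 of them. That table also gave the order of genes along chromosomes; no coordinates are given. Probe sets with a mean log2 value under 4, an intensity of 16, are called dim.

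Linear models were fitted to all 12 arrays with limma 3.58.1 in R 4.3.3, with 1 mean per group and empirical Bayes moderation (8 residual degrees of freedom, 8.8 with the prior). Contrasts gave the phenobarbital effect in each genotype, the genotype effect on each diet, the interaction, which is the difference between the phenobarbital effects, and the mean phenobarbital effect. A probe set was called at an adjusted p under 0.05 (Benjamini and Hochberg, over all probe sets of a contrast) and at least a 1.5-fold change. Shifts of 31 gene lists were tested with camera from limma in the 4 pairwise contrasts and the interaction, 155 tests adjusted together, at a preset correlation between genes of 0.01 and again with the correlation estimated from the data. Each gene entered a list through 1 probe set, and members were also adjusted over the list alone. The contrasts, the thresholds, the lists and the naming rule were set before the data were examined. By that rule the text could name Hr96, the 8 called genes with the largest rise and the 8 with the largest fall of each contrast, and up to 2 called members per list and direction; genes outside it were chosen after their values were seen.

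The scripts were tested on simulated data drawn from the means and spread of the real arrays. Of the probe sets given a change in wild type, the fit called 29.9% at 1.5-fold, 74.6% at 2-fold and 92.4% at 4-fold, with 7 false calls among 18769 probe sets. A list shifted by 0.5 on the log2 scale was called in 3 of 3 comparisons and 0 of 152 other list tests were. The simulated probe sets varied independently of each other, unlike those of the real arrays. These counts therefore check the scripts and do not give error rates for the real arrays.

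The fits were repeated with no minimum fold change, a 2-fold minimum, an intensity trend with a robust prior, quantile normalization, a filter on dim probe sets, array weights, the replicate number as a block, leaving out each array in turn and a fit on the 2 groups compared. The mean of the testis markers as a covariate was added after seeing the data, as was, for 1 count alone, the mean of 6 chorion genes. Arrays with the same replicate number were not treated as pairs. Other splits of the arrays into groups were fitted in the same way. Figures were drawn with Python 3.11.15, numpy 2.4.6 and matplotlib 3.10.9.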

Results

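Gene expression was measured in adult Drosophila melanogaster on 12 oligonucleotide arrays. The flies were either Canton S, a laboratory strain widely used as wild type, or mutants of DHR96, the nuclear receptor encoded by Hr96. They had been starved overnight and were then given sucrose alone or sucrose with 0.3% phenobarbital, a barbiturate used as a model inducer of drug-metabolising enzymes. Each combination of genotype and diet was measured on 3 arrays. The labels do not say whether the arrays of a group came from separate cultures of flies, so the p-values measure the spread between these arrays, which may be technical. Per array, the median intensity over 18769 probe sets lay between 38.5 and 47.5, and 44.4% to 45.6% of probe sets lay below a log2 value of 4, called dim here. The number of arrays limits the precision. Between 2 arrays of a group, the SD of the log2 differences was 0.24 to 0.53. The design asks how wild type responds to phenobarbital, how the mutant responds, whether the genotypes differ on each diet, and whether the response differs between genotypes.

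Hr96 was higher in every array labelled mutant than in every wild-type array. Its mean log2 value was 8.39 ± 0.17 in wild type on sucrose, 8.53 ± 0.29 in wild type on phenobarbital, 9.99 ± 0.07 in the mutant on sucrose and 10.24 ± 0.06 in the mutant on phenobarbital (SD, n = 3 each). The arrays labelled mutant were thus 3.03-fold above wild type on sucrose (adjusted p = 0.0022, limma) and 3.27-fold above it on phenobarbital (adjusted p = 0.0012). Phenobarbital itself gave no call for Hr96, with a log2 change of 0.14 ± 0.14 (SE) in wild type and 0.25 ± 0.14 in the mutant. The level of this transcript separates the genotypes as labelled. It does not show a loss of the receptor's function, since the labels do not describe the allele and the position of the probe set relative to it is not given in the sources used here; directions given for the mutant below are those of the arrays labelled mutant.

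**Figure D1:**
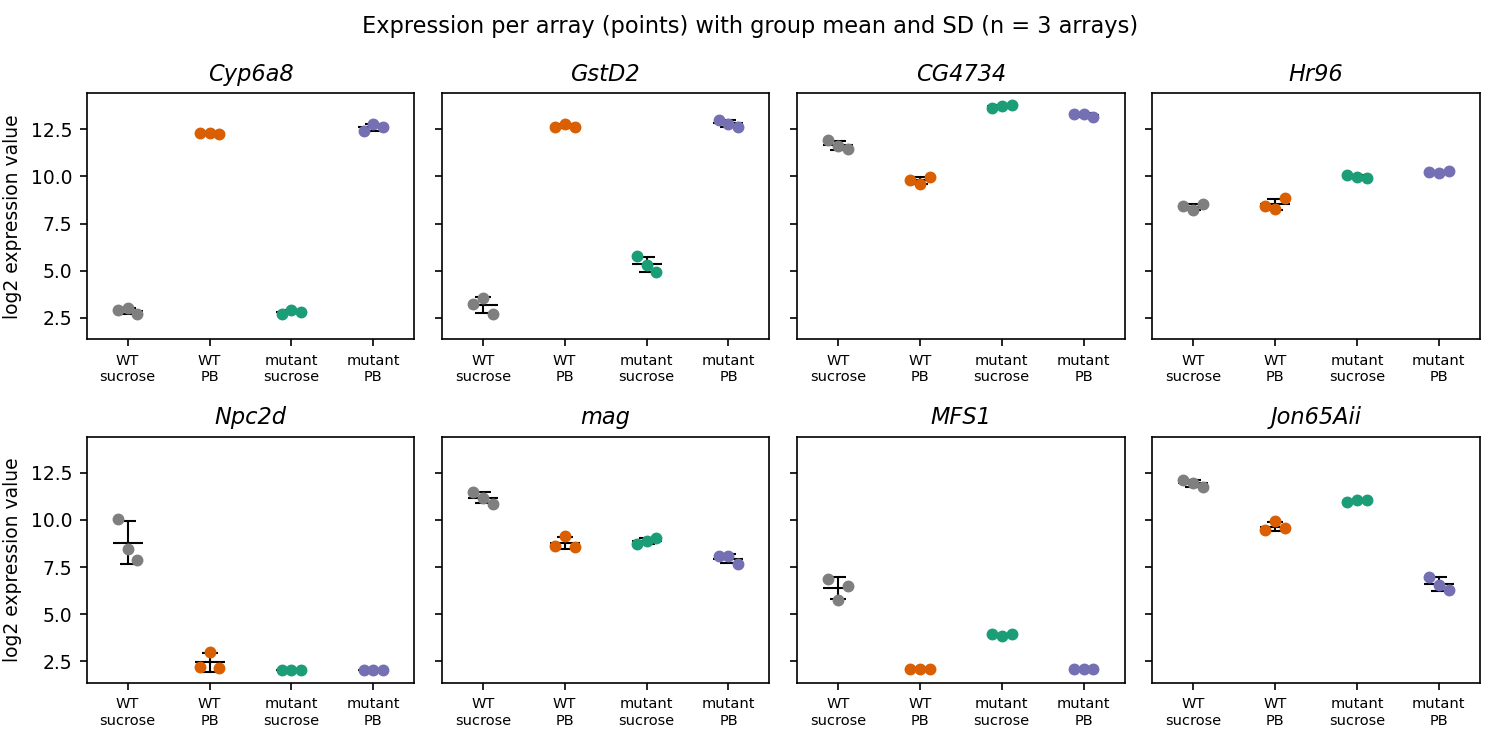
Log2 expression value (y axis) of 8 genes on each of the 12 arrays; points are arrays, bars are the group mean and SD (n = 3), WT is wild type and PB is phenobarbital. Cyp6a8 rose from 2.88 to 12.29 in wild type, Npc2d was at 2.04 in both mutant groups, and Hr96 was higher in the mutant on both diets.

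In wild type, phenobarbital raised single genes of drug-metabolising enzymes by up to 734-fold, and the largest falls included genes of the eggshell. The cytochrome P450 gene Cyp6a8 went from a dim log2 value of 2.88 ± 0.16 to 12.29 ± 0.03 (SD, n = 3), a 680-fold rise with an SE of 0.11 on the log2 scale. The glutathione S-transferase gene GstD2 rose 734-fold, from a dim 3.17 ± 0.42 to 12.69 ± 0.11, and GstD7 rose 78.1-fold, from a dim 2.68 ± 0.22 to 8.97 ± 0.27. Vm34Ca and Vm26Aa, which encode proteins of the vitelline membrane around the egg, were 106-fold and 75.5-fold lower. Their arrays on sucrose spread widely: Vm34Ca went from 11.01 ± 2.19 to 4.29 ± 0.84 and Vm26Aa from 10.45 ± 1.61 to 4.21 ± 0.05. Npc2d, of the sterol-binding NPC2 family, dropped from 8.79 ± 1.15 to a dim 2.44 ± 0.49. A fold taken against a dim group depends on the background model of the normalization.

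Of the 18769 probe sets, 801 were called, 426 higher and 375 lower on phenobarbital (limma, adjusted p under 0.05 and at least 1.5-fold). They represented 384 genes that rose and 339 that fell. The other large rises were in hll (log2 change 7.77 ± 0.30, SE), CG34040 (7.50 ± 0.56), the glycine methyltransferase gene Gnmt (6.48 ± 0.45), the diacylglycerol acyltransferase gene Dgat2 (6.06 ± 0.26) and Cyp6a21 (5.65 ± 0.15), with adjusted p from 1.5e-07 to 7e-05. The other large falls were in CG12057 (-5.89 ± 0.82), fit (-5.55 ± 0.46), CG10514 (-5.21 ± 0.50), phu (-5.19 ± 0.28) and CG11892 (-5.09 ± 0.52), with adjusted p from 1.2e-05 to 0.0026. On sucrose hll and Dgat2 were dim (2.81 and 2.68), and on phenobarbital CG12057, fit, CG10514 and phu were (3.97, 3.30, 3.46 and 2.88). Fit is a female-biased gene of the fat body. When only the 6 arrays of these 2 groups were fitted, 391 probe sets were called, Vm34Ca no longer among them.

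Members of several families of drug-metabolising enzymes rose in wild type, and fewer fell. Of 81 measured P450 genes, 30 rose and 4 fell, or 34 and 7 adjusted over the list alone; the largest fall was in Cyp4d21 (-3.39 ± 0.60), to a dim 3.26. The P450 list lay higher than other genes (median 0.41; camera adjusted p = 2.04e-11; adjusted p = 0.372 with an estimated correlation). Among 36 glutathione S-transferase genes, 17 rose and GstE10 alone fell (-0.95 ± 0.20), or 20 and 1 adjusted over the list alone (median 0.65; adjusted p = 7.91e-13, and adjusted p = 0.296 with an estimated correlation). Among 35 UDP-glycosyltransferase genes, which attach sugars to drugs, 8 rose and 1 fell, or 11 and 3 adjusted over the list alone. Ugt35C1 rose by 4.72 ± 0.38 and Ugt37A2 by 4.27 ± 0.18 on the log2 scale (list adjusted p = 1.86e-05, and adjusted p = 0.296 with an estimated correlation). Carboxylesterases gave 4 rises and no fall among 13, led by Est-Q and alpha-Est7 (2.35-fold and 2.34-fold; list adjusted p = 0.00138, and adjusted p = 0.376 with an estimated correlation). Carbonyl and alcohol redox enzymes gave 5 rises among 10, with Sodh1 up 8.71-fold and CG12766 up 8.51-fold (list adjusted p = 5.02e-07, and adjusted p = 0.296 with an estimated correlation). Adjusted over the list alone, the counts were 5 and 1 for the esterases and 5 and 0 for the redox enzymes.

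Single genes of oxidative stress, transport and hormone turnover were also called, and of these lists only the first was past the threshold. Keap1, the cytoplasmic sensor of electrophiles, rose 4.70-fold and the peroxidase gene Gtpx 2.01-fold, 2 of 4 rises among 16 glutathione and antioxidant genes (4 adjusted over the list alone; list adjusted p = 2.61e-05, and adjusted p = 0.372 with an estimated correlation). Among 15 drug and organic anion transporters, Mdr50 rose 6.30-fold and MRP 2.68-fold, while 3 fell, among them Oatp58Da (-1.20 ± 0.12) and Mrp5 (-1.01 ± 0.10). This list as a whole was not past the threshold (adjusted p = 0.767). Jheh2, an epoxide hydrolase of juvenile hormone, rose 6.87-fold with an SE of 0.06 on the log2 scale, and the hormone-response gene Kr-h1 fell by 0.84 ± 0.10 in the same list of 8 genes (list adjusted p = 0.84).

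**Figure D2:**
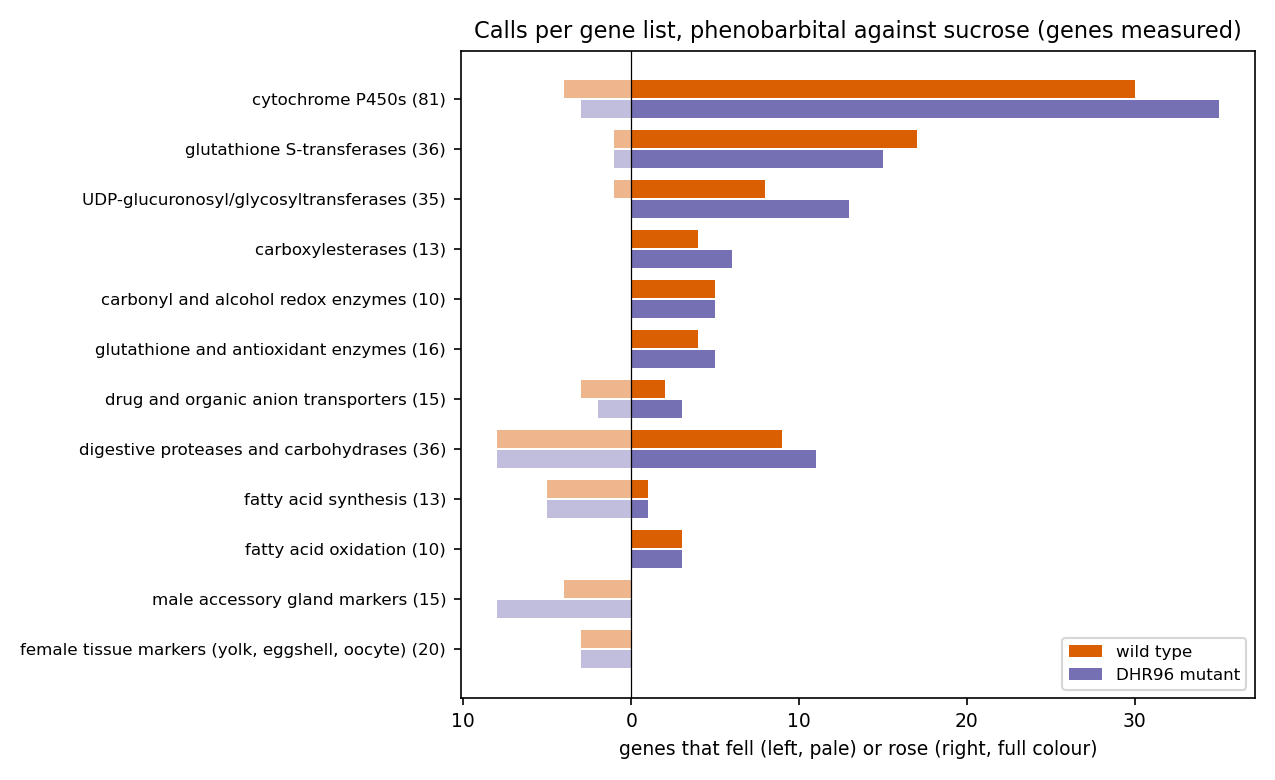
Number of genes called higher (right) or lower (left, pale) on phenobarbital in 12 gene lists, with the number of measured genes in parentheses; orange is wild type and purple is the DHR96 mutant. In wild type 30 of 81 P450 genes rose and 4 fell, and in the mutant 35 rose and 3 fell.

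Metabolic genes also moved in wild type on phenobarbital. Pepck1, of gluconeogenesis, rose 10.2-fold and the alpha-glucosidase gene tobi 15.3-fold, while the sugar-responsive factor sug fell by 1.36 ± 0.18 and the activin-like ligand daw by 0.86 ± 0.15 (log2, SE). These belong to a list of 13 fasting genes that was not past the threshold (3 rose, 2 fell; adjusted p = 0.223). Of 13 fatty acid synthesis genes 5 fell, among them FASN1 (-1.90 ± 0.10) and FASN3 (-1.44 ± 0.16), and the acyltransferase gene mdy rose by 1.43 ± 0.14 (list median 0.02, mean -0.24, tested as lower; adjusted p = 0.393). Of 10 fatty acid oxidation genes 3 rose, among them the peroxisomal oxidase gene Acox57D-p (4.52-fold) and the thiolase gene yip2 (2.29-fold); the list lay higher (adjusted p = 5.75e-07, and adjusted p = 0.372 with an estimated correlation). In the 17 genes of glycolysis and sugar storage, Hex-C rose by 1.16 ± 0.18 and 3 genes fell, among them Glyp (-0.79 ± 0.07) and Tps1 (-0.67 ± 0.10; list adjusted p = 0.012, and adjusted p = 0.693 with an estimated correlation). Digestive enzymes moved both ways, 9 rising and 8 falling among 36, with the maltase genes Mal-B1 and Mal-A3 up 12.2-fold and 11.9-fold and the protease genes Jon99Fi and Jon65Ai down 11.8-fold and 5.15-fold (list median -0.12, mean 0.15, tested as lower; adjusted p = 0.36). Among 13 genes of dietary lipid and sterol uptake, Npc2d and the intestinal lipase gene mag fell, mag 5.26-fold (list adjusted p = 0.185).

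Markers of other tissues moved too. The accessory gland of the male gave 4 falls among 15 markers, or 12 adjusted over the list alone, including Acp76A (-2.45 ± 0.45) and Acp29AB (-1.71 ± 0.37; list median -1.05; adjusted p = 2.65e-08, and adjusted p = 0.513 with an estimated correlation). The list of female tissue markers, which holds yolk, eggshell and oocyte genes and fit, gave 3 falls among 20. These were Vm34Ca, Vm26Aa and fit (list median -1.06, camera adjusted p = 0.00348, and adjusted p = 0.529 with an estimated correlation). The list of 66 oxidative phosphorylation genes lay lower without any single call (median -0.25; adjusted p = 3.78e-07, and adjusted p = 0.627 with an estimated correlation). Flight muscle markers (median -0.30; adjusted p = 0.00124, and adjusted p = 0.513 with an estimated correlation), photoreceptor markers (-0.23; adjusted p = 0.0261, and adjusted p = 0.693 with an estimated correlation) and hemocyte markers (-0.44; adjusted p = 0.0122, and adjusted p = 0.513 with an estimated correlation) also lay lower; of these only Col4a1 and vkg, the collagen IV genes, were called, at -0.88 ± 0.13 and -0.84 ± 0.12. Proteasome genes lay slightly higher (0.15; adjusted p = 0.00863, and adjusted p = 0.562 with an estimated correlation). Immune genes gave 5 rises and 2 falls among 29, with the antimicrobial peptide gene Mtk up 7.17-fold, PGRP-LB up 2.69-fold and Drsl5 down 2.03-fold (adjusted p = 0.0348, and adjusted p = 0.693 with an estimated correlation). Of 5 Turandot stress genes only TotC rose, 12.0-fold (adjusted p = 0.0261, and adjusted p = 0.513 with an estimated correlation). Not past the list threshold were odorant-binding proteins (3 rose, 3 fell of 47), Malpighian tubule markers (ry and salt rose, Irk3 fell, of 9), testis markers (17 genes), fat body markers (5), nuclear receptors (20), ribosomal proteins (41), heat shock proteins and chaperones (16) and clock genes (8), with adjusted p between 0.0522 and 0.695 and no call in the last 6. Median and mean differed in sign for Malpighian tubule markers (-0.19 and 0.19), ribosomal proteins (0.03 and -0.02) and nuclear receptors (0.02 and -0.001); for chaperones both were negative (-0.04 and -0.009) while camera placed the list higher.

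Many of the largest changes in the mutant on phenobarbital were in genes that also led in wild type. Cyp6a8 rose 883-fold (log2 change 9.79 ± 0.11, SE), GstD2 178-fold (7.47 ± 0.24), GstD7 85.8-fold (6.42 ± 0.22) and Cyp6a21 68.2-fold (6.09 ± 0.15). In the mutant hll rose by 6.38 ± 0.30, CG14957 by 6.21 ± 0.18 and Gnmt 64.1-fold. Vm26Aa (-8.17 ± 0.77), Vm34Ca (-7.85 ± 1.06), fit (-6.72 ± 0.46), CG11892 (-5.36 ± 0.52), CG6788 (-4.80 ± 0.32), phu (-4.47 ± 0.28) and the protease genes Jon99Fi (-4.44 ± 0.22) and Jon65Aii (-4.41 ± 0.19) fell most. Cyp6a8, GstD7, hll and CG14957 were dim on sucrose (2.83, 3.15, 2.61 and 3.01), and Vm26Aa, fit, CG6788 and phu on phenobarbital (3.70, 2.81, 2.74 and 2.86). Limma called 867 probe sets, 579 higher and 288 lower, which stood for 518 and 269 genes. The lower calls depended on single arrays, with 176 without mutant sucrose replicate 3, 177 without mutant phenobarbital replicate 3 and 186 without mutant sucrose replicate 1. With estimated array weights 977 were called higher and 1582 lower, a fit in which 1 mutant array on sucrose took nearly all the weight.

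By list, 35 of 81 P450 genes rose and 3 fell in the mutant (adjusted p = 2.69e-10, and adjusted p = 0.372 with an estimated correlation), as did 15 and 1 of 36 glutathione S-transferases (adjusted p = 3.45e-11, and adjusted p = 0.296 with an estimated correlation) and 13 and 0 of 35 UDP-glycosyltransferases (adjusted p = 1.68e-05, and adjusted p = 0.296 with an estimated correlation). Adjusted over the list alone, these were 39 and 4, 17 and 1, and 14 and 3. Carboxylesterases gave 6 rises, among them alpha-Est7 and alpha-Est10 (2.77-fold and 2.69-fold), and Sodh1 rose 10.6-fold, Mdr50 8.86-fold, Jheh2 6.78-fold and Keap1 5.75-fold. Pepck1 rose by 3.64 ± 0.12 and tobi by 3.31 ± 0.30, FASN1 fell by 1.82 ± 0.10, sug by 2.12 ± 0.18 and daw by 1.21 ± 0.15. In the lipid and sterol uptake list mag (-0.95 ± 0.21), Npc2g (-1.09 ± 0.17) and Npc2h (2-fold) fell, and Npc2d was at a dim 2.04 on both diets. Accessory gland markers gave 8 falls among 15 (adjusted p = 9.32e-10, and adjusted p = 0.502 with an estimated correlation), and the 17 testis markers lay lower with no single call (median -0.72; adjusted p = 5.65e-05, and adjusted p = 0.614 with an estimated correlation). Lsp2, a storage protein of the fat body, rose from 5.81 ± 1.48 to 11.81 ± 0.61 (SD, n = 3).

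The overlap of both responses was large. Of the calls, 403 probe sets were higher and 221 lower in both genotypes, none moved in opposite directions, and independent lists of these sizes would share 13.1 and 5.8. Across probe sets, which are not independent replicates, the log2 changes correlated at r = 0.855; the comparisons share no array. Averaged over both genotypes, phenobarbital gave 1070 calls, 565 higher and 505 lower, and 1069 of them changed in the same direction in both. Selection on the mean largely fixes this agreement in advance, since opposite changes cancel in it. The median absolute log2 change of the 1070 was 1.09 in wild type and 1.12 in the mutant. Of 177 probe sets called in wild type only, 164 changed in the same direction in the mutant. Of 243 called in the mutant only, 240 did so in wild type.

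**Figure D3:**
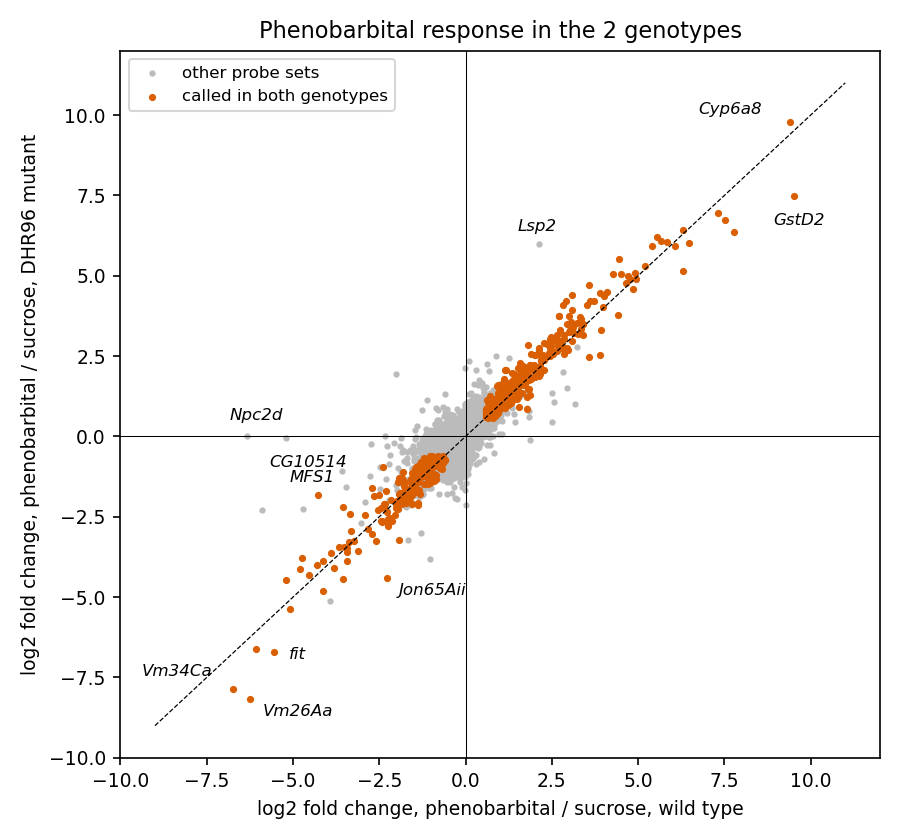
Log2 fold change on phenobarbital in the DHR96 mutant (y axis) against that in wild type (x axis) for all 18769 probe sets; orange points were called in both genotypes and the dashed line marks equal change. Cyp6a8 and GstD2 lie at the top right, Vm26Aa and Vm34Ca at the bottom left, and Npc2d and CG10514 lie near 0 on the mutant axis.

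Limma called no probe set for a difference between the 2 responses, with 624 at an unadjusted p under 0.05 and a smallest adjusted p of 0.072. With an intensity trend and a robust prior 7 were called: Npc2d (difference 6.35 ± 0.65, SE; adjusted p = 0.014), CG10514 (5.15 ± 0.66; adjusted p = 0.033), the transporter gene MFS1 (2.44 ± 0.31; adjusted p = 0.029), CG4734, the cuticle gene Cpr66D, which was dim in all groups, the protease gene Jon65Aii (-2.12 ± 0.26; adjusted p = 0.026) and a probe set with no gene name; they were named after their values were seen. With array weights 5 were called. Npc2d, CG10514 and MFS1 fell on phenobarbital in wild type, and in the mutant Npc2d and CG10514 were already dim on sucrose, at 2.04 ± 0.01 and 2.24 ± 0.04 (SD, n = 3), so no further fall could be read there. MFS1 was dim in the mutant on sucrose (3.91) and in wild type and mutant on phenobarbital (2.11 and 2.09). Its falls could thus be read only in part. Leaving out wild-type sucrose replicate 3 gave 15 calls, and leaving out any other array gave 0 to 3.

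On sucrose, the arrays labelled mutant differed from wild type in few called genes, and the largest called differences were lower levels of Npc2d and CG10514. Npc2d and CG10514 were dim in the mutant and well measured in wild type, at 8.79 ± 1.15 and 8.67 ± 0.47 (SD, n = 3), with log2 differences of -6.75 ± 0.48 and -6.43 ± 0.50 (SE). The transporter gene MFS1 was 5.53-fold lower and the lipase gene mag 4.91-fold lower. CG10300 (-1.97 ± 0.19), the protease gene CG11912 (-1.90 ± 0.22), uif (-1.45 ± 0.19) and the lipophorin receptor gene LpR1 (-1.51 ± 0.19) followed. MFS1 was dim in the mutant (3.91), as was CG10300, and uif was dim in both genotypes (3.82 and 2.37). Higher in the mutant were GstD2 (5.35 ± 0.41 against a dim 3.17 ± 0.42, SD), CG4734 (4.23-fold), CG7953 (3.16-fold), CG8997 (2.46-fold), CG5770 (2.51-fold) and Hr96 with the genes on either side of it in chromosome order, EMC6 (3.03-fold) and Smg6 (2.58-fold). A brighter probe set of LpR1, with a mean log2 value of 10.07, gave -0.22 ± 0.05 and no call (adjusted p = 0.12), so the probe sets of this gene disagree; the second probe sets of uif and gce were dim and gave no call.

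Limma called 40 probe sets on sucrose, 11 higher and 29 lower, and among the named ones the adjusted p ran from 3.5e-05 for Smg6 to 0.042 for gce. Other called members of the lists were alpha-Est9 (-1.17 ± 0.16), the juvenile hormone receptor gene gce (-1.23 ± 0.19) and Mrp5 (-0.65 ± 0.10). No single P450 gene was called. Of the lists past the threshold, oxidative phosphorylation (median -0.33; adjusted p = 7.91e-13, and adjusted p = 0.513 with an estimated correlation), digestive enzymes (-0.18; adjusted p = 6.45e-05, and adjusted p = 0.502 with an estimated correlation), glycolysis (-0.25; adjusted p = 1.98e-06, and adjusted p = 0.502 with an estimated correlation) and dietary lipid uptake (-0.05; adjusted p = 0.0323, and adjusted p = 0.513 with an estimated correlation) lay lower in the mutant, and female tissue markers lay higher (1.32; adjusted p = 2.85e-06, and adjusted p = 0.389 with an estimated correlation). Also higher were ribosomal proteins (0.10; adjusted p = 5.24e-07, and adjusted p = 0.502 with an estimated correlation) and proteasome subunits (0.16; adjusted p = 1.68e-05, and adjusted p = 0.426 with an estimated correlation). Clock genes (-0.38; adjusted p = 0.000128, and adjusted p = 0.372 with an estimated correlation), juvenile hormone turnover (-0.38; adjusted p = 0.000903, and adjusted p = 0.296 with an estimated correlation), hemocyte markers (-0.36; adjusted p = 0.00128, and adjusted p = 0.49 with an estimated correlation) and flight muscle markers (-0.20; adjusted p = 0.00139, and adjusted p = 0.513 with an estimated correlation) lay lower. Fasting genes lay lower too (-0.35; adjusted p = 0.0385, and adjusted p = 0.372 with an estimated correlation). Smaller shifts down were found for P450s (-0.06; adjusted p = 0.0138, and adjusted p = 0.684 with an estimated correlation), UDP-glycosyltransferases (-0.07; adjusted p = 0.0139, and adjusted p = 0.502 with an estimated correlation) and carboxylesterases (-0.05; adjusted p = 0.0347, and adjusted p = 0.513 with an estimated correlation). Immune genes also shifted down (-0.14; adjusted p = 0.0319, and adjusted p = 0.693 with an estimated correlation). Mean log2 values of 6 chorion genes, which encode the outer eggshell, were 7.64 ± 4.16 in wild type and 11.45 ± 0.66 in the mutant on sucrose (SD, n = 3), and those of the 17 testis markers were 9.81 ± 0.39 and 9.87 ± 0.35. The count depended on single arrays: 19 without mutant sucrose replicate 1, 25 and 26 without mutant phenobarbital replicates 1 and 2, and 185 without wild-type sucrose replicate 3; without mutant sucrose replicate 3 the lower calls went from 29 to 19. With the testis marker mean as a covariate, chosen after seeing the data, 76 were called, and a fit of these 2 groups alone called 4.

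Of the 29 probe sets lower in the mutant on sucrose, 15 were also among the 375 lowered by phenobarbital in wild type, where independent lists would share 0.6. Both comparisons use the wild-type sucrose arrays, which gives them shared chance values: in 100 simulations of unchanged groups the simulated correlation of log2 changes was 0.498 against 0.215 observed, and the simulated covariance was 0.0197 against 0.0313 observed, a difference of 0.0116. The simulated probe sets varied independently of each other, unlike the real ones. The controls could not be split with 3 arrays, and part of the excess may come from them. The shared count also depended on single arrays, with 6 without mutant sucrose replicate 1, 78 without wild-type sucrose replicate 3, 23 without its replicate 1 and 11 to 21 without any other. With array weights it was 44, with the testis marker covariate, an intensity trend and a robust prior 40, with no minimum fold change 25 and at a 2-fold minimum 9. All 15 were lower on each of the other 9 arrays than on any wild-type sucrose array, which for 6 of the 9 follows largely from their selection. They include Npc2d, CG10514, MFS1, mag, CG10300, CG11912, LpR1, uif and Mrp5. Their median group means were 6.37 in wild type on sucrose, 4.40 in wild type on phenobarbital, 4.51 in the mutant on sucrose and 3.83 in the mutant on phenobarbital. In the mutant, phenobarbital lowered 3 of the 15 further by the same criteria. Npc2d, CG10514, uif, CG31097, Cpr66D, CG10300 and MFS1 were already dim in the mutant on sucrose, at 2.04 to 3.91. A further fall could be read in them only in part or not at all. The count of 3 therefore does not show a lost response.

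On phenobarbital, the arrays labelled mutant had lower levels of 2 proteases and 2 NPC2 genes and higher levels of a storage protein. Jon65Aii was 8.26-fold lower (-3.05 ± 0.19, SE), Jon99Fi 4.69-fold (-2.23 ± 0.22), Npc2h 3.88-fold (-1.95 ± 0.20) and Npc2g 2.97-fold (-1.57 ± 0.17). The sugar-responsive gene sug (-1.24 ± 0.18), alpha-Est9 (-1.20 ± 0.16), CG13784 (-0.97 ± 0.07) and a probe set of the pyruvate carboxylase gene PCB (-0.83 ± 0.11) were also lower. A brighter probe set of PCB, with a mean log2 value of 12.31, gave -0.15 ± 0.05 and no call (limma, adjusted p = 0.37). The probe sets of PCB thus disagree. For CG13784, 2 other probe sets gave no call. Lsp2 was higher in the mutant, at 11.81 ± 0.61 against 5.29 ± 1.26 in wild type (SD, n = 3), a log2 difference of 6.52 ± 0.80 (SE). CG4734 (3.46 ± 0.13), CG7953 (2.30 ± 0.17), CG8997 (1.89 ± 0.14), Hr96 (1.71 ± 0.14), Ugt37A3 (1.58 ± 0.20), EMC6 (1.55 ± 0.09) and CG7916 (1.41 ± 0.19) were higher as well.

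Limma called 22 probe sets on phenobarbital, 14 higher and 8 lower, and 10 of these were called in the same direction on sucrose, 8 higher and 2 lower. Among the named ones the adjusted p ran from 1.9e-05 for CG4734 to 0.047 for sug. No P450 or glutathione S-transferase gene was among the 22. Lists past the threshold and lower in the mutant were oxidative phosphorylation (median -0.24; adjusted p = 2.11e-11, and adjusted p = 0.513 with an estimated correlation), testis markers (-0.49; adjusted p = 8.13e-05, and adjusted p = 0.617 with an estimated correlation), and juvenile hormone turnover (-0.30; adjusted p = 0.00181, and adjusted p = 0.296 with an estimated correlation). Immune genes were lower as well (-0.20; adjusted p = 0.00184, and adjusted p = 0.562 with an estimated correlation). The same held for clock genes (-0.18; adjusted p = 0.0249, and adjusted p = 0.514 with an estimated correlation). Odorant-binding proteins (-0.03; adjusted p = 0.00323, and adjusted p = 0.513 with an estimated correlation), digestive enzymes (-0.04; adjusted p = 0.0122, and adjusted p = 0.643 with an estimated correlation) and Turandot genes (-0.05; adjusted p = 0.0221, and adjusted p = 0.502 with an estimated correlation) lay slightly lower. Female tissue markers (0.58; adjusted p = 0.00999, and adjusted p = 0.584 with an estimated correlation), proteasome subunits (0.16; adjusted p = 0.0236, and adjusted p = 0.627 with an estimated correlation) and ribosomal proteins (0.07; adjusted p = 0.00438, and adjusted p = 0.686 with an estimated correlation) lay higher. Mean log2 values of the chorion genes were 4.78 ± 2.22 in wild type and 10.11 ± 2.71 in the mutant, and those of the testis markers 9.65 ± 0.32 and 9.20 ± 0.34 (SD, n = 3). The calls of Lsp2 and Ugt37A3 were lost with the testis marker covariate and without several single arrays, and that of sug without 11 of the 12 arrays in turn. The higher calls went from 14 to 22 without wild-type phenobarbital replicate 3 and to 9 without its replicate 1, and the lower ones from 8 to 5 without mutant sucrose replicate 1 or mutant phenobarbital replicate 2.

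**Figure D4:**
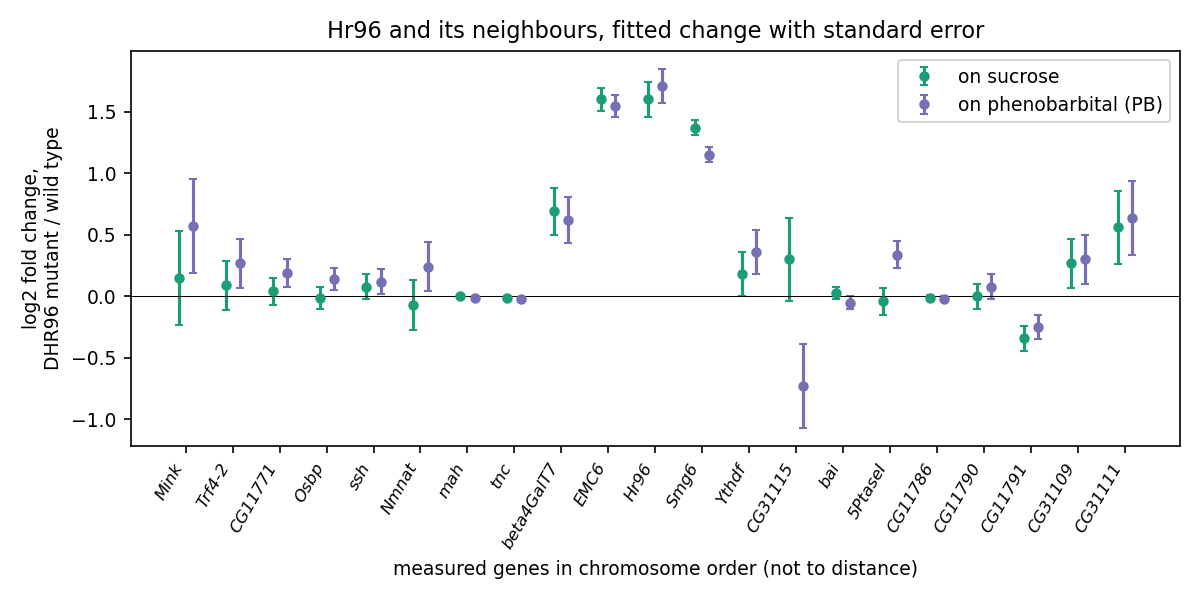
Log2 fold change of the DHR96 mutant against wild type (y axis, fitted value with SE) for Hr96 and the 10 measured genes on each side of it in chromosome order (x axis, not to distance), on sucrose (green) and on phenobarbital (purple). EMC6, Hr96 and Smg6 lie between 1.15 and 1.71 on both diets and were the genes called; the remaining 18 were not.

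Reproductive tissue markers varied between arrays of 1 group. Within groups, 61.2% of the variance over 10341 probe sets with a mean log2 value of at least 4 lay on a single axis. The axis was broad, with a median absolute correlation of 0.73 over these probe sets. Testis markers (0.94, 94% positive), accessory gland markers (0.81, 100%) and photoreceptor markers (0.80, 100%) moved with it. Clock genes (0.72, 88%) and Malpighian tubule markers (0.62, 89%) were also mostly positive, but their correlations were below that median. Proteasome subunits (0.88, 35% positive), chaperones (0.85, 44%) and ribosomal proteins (0.81, 17%) followed it with members of both signs. Chorion genes ranged from a mean of 2.84 to 10.24 among the 3 wild-type sucrose arrays.

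**Figure D5:**
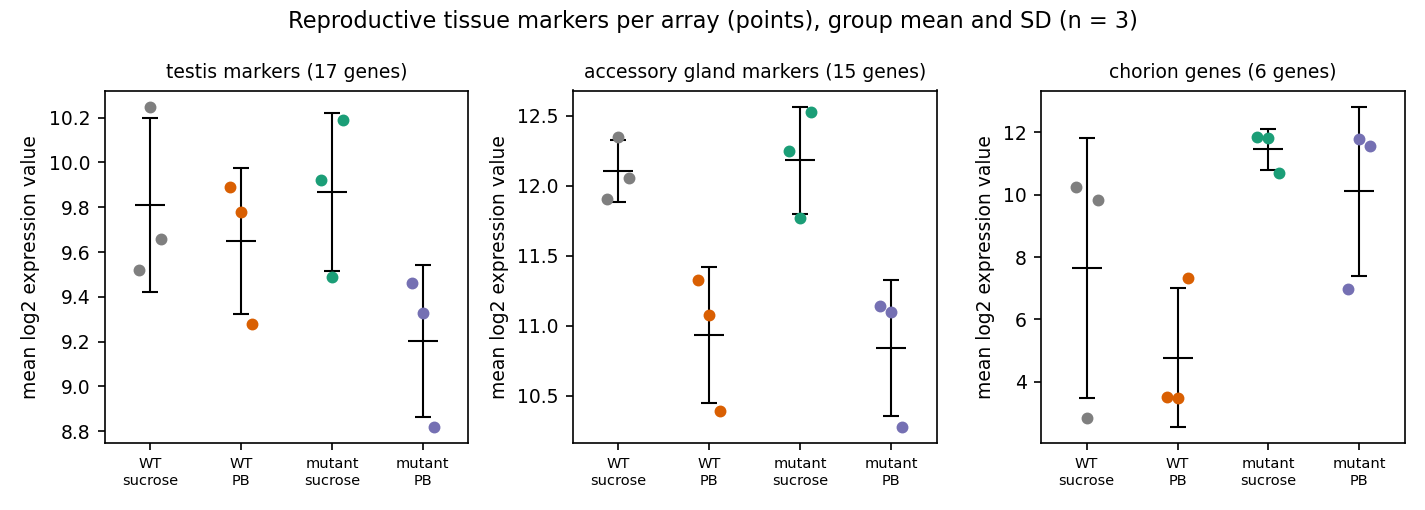
Mean log2 expression value per array (points) of 17 testis markers, 15 accessory gland markers and 6 chorion genes, with the group mean and SD (n = 3); WT is wild type and PB is phenobarbital. Accessory gland means were 12.11 and 12.18 on sucrose and 10.93 and 10.84 on phenobarbital, and chorion genes spanned 2.84 to 11.84 over all arrays.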

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

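The tests of Hr96's neighbours, of the shared lower genes, of the testis markers and of array brightness in this part were chosen after the results were seen; the tests of other splits, strain DNA and ovary tissue were set before.

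The shift of 7 gene lists differed between the phenobarbital responses of the genotypes by the interaction test at the preset correlation, and each lost its call with an estimated correlation. The P450 list responded more in the mutant (median difference 0.171; adjusted p = 0.015; adjusted p = 0.69 with an estimated correlation), as did drug and organic anion transporters (0.301; adjusted p = 0.002; 0.37 estimated), UDP-glycosyltransferases (0.199; adjusted p = 0.0046; 0.46 estimated) and glycolysis and sugar storage (0.212; adjusted p = 0.0035; 0.65 estimated). Testis markers lay lower (-0.567; adjusted p = 1.3e-06; 0.51 estimated), as did Turandot genes (-0.066; adjusted p = 0.012; 0.49 estimated) and odorant-binding proteins (-0.02; adjusted p = 0.021; 0.62 estimated). With the testis marker covariate the adjusted p was 0.00049 for P450s, 0.0025 for transporters, 0.025 for glycosyltransferases, 0.022 for glycolysis, 0.1 for Turandot genes and 0.64 for odorant-binding proteins. For the testis markers themselves, their own mean as the covariate removes the difference by construction.

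Hr96, EMC6 and Smg6 lie next to each other and were higher in the mutant on both diets. A change of the Hr96 transcript alone predicts no call next to it, while 2 of 2 adjacent genes were called on both diets. The difference was thus not confined to Hr96. This prediction was written after those calls were seen, so it describes them and is no separate test. Altered DNA at the locus, such as extra copies, stayed open as a hypothesis. Of the other 18 measured genes within 10 places 0% were called on both diets, but this test restates the values that prompted it. Without a call, beta4GalT7, beside EMC6, was higher by 0.69 ± 0.19 on sucrose and 0.62 ± 0.19 on phenobarbital (log2, SE). Ythdf, beside Smg6, was at 0.18 ± 0.18 and 0.36 ± 0.18. The calls thus do not show where the rise ends. Genomic DNA would have to test the hypothesis. DNA of another strain around Hr96 also met its prediction, with 6 of 400 window genes called on sucrose against 29 of 11581 others (odds ratio 6.06, 95% interval 2.05 to 14.97, Fisher p = 0.00095). CG10300, CG10514, CG31097 and LpR1, 4 of the 6, also fell on phenobarbital in wild type. A strain difference neither predicts nor forbids such falls, and both comparisons use the wild-type sucrose arrays. The falls therefore decide nothing about strain DNA. On phenobarbital none of the 4 was called between genotypes. CG10300, CG10514 and CG31097 were dim there in wild type (2.33 to 3.5), so a lower level in the mutant could hardly be read. LpR1 was not dim there and differed by -0.29. The other 2 of the 6 called window genes were EMC6 and Smg6, the neighbours of Hr96 treated above. Fisher's test takes genes as independent, while CG10514 and CG31097 lie close together, 54 and 62 places from Hr96. Its p may therefore be too small.

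The spread between arrays of a group lay mainly on 1 axis, with 61.2% of the within-group variance. An unequal share of male germ line stayed open: the testis markers had a median absolute correlation with the axis of 0.94, but all probe sets of the axis had 0.73, proteasome subunits 0.88, chaperones 0.85, accessory gland markers 0.81 and photoreceptor markers 0.80. Other lists thus followed the axis too. Whether they hold genes active in the germ line was not examined. The mean of the testis markers followed the axis at r = 0.96 (rho 0.93; permutation p = 1e-05, 3e-05 adjusted over 3 relations; r = 0.95 without the 2 arrays farthest out). An unequal share of ovary tissue stayed undecided (median absolute correlation 0.54, 11 of 17 of 1 sign). The 17 are the female markers other than yolk and include fit, a gene of the fat body. Their mean followed the axis at r = -0.85 (rho -0.83, permutation p = 0.00086, 0.0013 adjusted, and r = -0.75 without the 2 farthest). Array brightness was undecided (r = 0.66; rho 0.71; permutation p = 0.021, adjusted 0.021; 0.79 without the 2 farthest). The axis was computed from the same log2 values, including those of markers that were not dim, so part of each correlation may be built in. The permutations also treated the arrays as exchangeable, while subtracting group means ties the values of a group together. These p-values are therefore likely too small, and no conclusion is drawn from them.

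The cause of the 15 genes low in the mutant on sucrose and in wild type on phenobarbital stayed open. For chance values of the shared wild-type sucrose arrays, 0 of 100 simulations gave as many shared lower calls, but unchanged groups gave at most 1 call in either comparison, so this count decides nothing. For an unequal share of male tissue, 100% stayed called with the testis marker covariate, but the testis mean hardly differed between these groups (9.81, 9.65 and 9.87). For egg-bearing female tissue, whose markers moved in opposite directions in the 2 comparisons, 46.7% of the 15 stayed called with the chorion gene mean as a covariate, while the median log2 changes went from -1.14 to -1.14 (SE 0.18) and from -1.45 to -1.32 (SE 0.20), so the loss of calls, which by itself met what was written for this cause, was not taken to decide it. A role of DHR96, the biological difference in the design, was not tested.

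Splits of the 6 arrays of each pair of groups show only whether chance can be excluded, and 10 splits are too few for a share under 0.05. Only the real split, 1 of 10, gave as many calls for phenobarbital in wild type (801, highest other 37), for phenobarbital in the mutant (867, highest other 1), for genotype on sucrose (40, highest other 2) and for genotype on phenobarbital (22, highest other 0). For the mean phenobarbital effect 1 of 100 splits, the real one, reached 1070 calls (highest other 46), the smallest share this test can give. A random split of these arrays is thus unlikely at 0.05 to give as many calls. Chance differences between cultures of flies were not tested by it. For the interaction 100 of 100 splits had at least the 0 calls of the real one, so this decides nothing. The highest other had 134, and the cause of that count was not tested.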

How the results depend on the processing

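Of 3756 alternative values for 171 named gene results, 3473 kept their status, 283 lost the call and 0 turned direction. For Hr96 under phenobarbital in each genotype and in the interaction, the status kept was the absence of a call. The setting with no minimum fold change could not lose a call. Called genes were named by the size of their change, so these totals do not stand for all calls. Of 1131 alternative values for 63 list shifts, 931 kept the call, 198 lost it and 2 turned direction. Only the testis marker covariate settings were chosen after seeing the data, and the cause of the changes below was not tested. At a 2-fold minimum, phenobarbital gave 506 calls in wild type, 550 in the mutant and 608 for the mean effect, against 1835 with no minimum. A fit on the 2 groups compared has fewer arrays and gave 391 calls for phenobarbital in wild type, 4 for genotype on sucrose and 11 for genotype on phenobarbital. Array weights gave 2559 calls for phenobarbital in the mutant, 172 for genotype on sucrose, 74 for genotype on phenobarbital and 5 for the interaction; their estimate did not converge, and 1 array took a weight of 104. An intensity trend with a robust prior gave 34 calls for genotype on phenobarbital and 7 for the interaction. With the testis marker covariate, genotype on sucrose gave 76 calls, or 121 with the trend and robust prior, where the interaction gave 1. Leaving out 1 array gave 19 to 185 calls for genotype on sucrose and 0 to 15 for the interaction. The 63 list shifts became 0 with an estimated correlation, and 0 with the testis marker covariate added to it; with that covariate alone 47 held, 15 lost the call and 1 turned; the interaction of odorant-binding proteins turned to 0.013 with the covariate at either correlation. With the replicate number as a block (replicate block) the counts were 718, 763, 32, 16, 0 and 997, in the order of the contrasts in the methods, and 67 list shifts. Of 18 pairs of arrays with the same number 7 correlated above 0.1 (range -0.71 to 0.70), and 5 of 12 arrays correlated best with their own number. These values show no clear pairing by number, and they cannot exclude one. Of 8 named results with another probe set of the gene, 2 were called there too and 6 were not. Dim probe sets limit what can be read as a fall.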

Other observations

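The tests of food intake were set before the results were seen, and the other values in this part were chosen afterwards.

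CG8997, CG7916 and CG7953 are consecutive genes on the chromosome, and all were higher in the mutant on phenobarbital. CG7953 was higher by 2.30 ± 0.17 (log2, SE), CG8997 by 1.89 ± 0.14 and CG7916 by 1.41 ± 0.19, with 3 arrays per group. CG4734 fell on phenobarbital from 11.65 to 9.80 in wild type and was at 13.73 and 13.25 in the mutant, the largest genotype difference among called probe sets on phenobarbital after Lsp2. Of the 565 probe sets that rose in the mean effect, 434 had the larger estimate in the mutant, and of 505 that fell 259 had it in wild type. These tallies of dependent probe sets were not tested; the median sizes were 1.09 in wild type and 1.12 in the mutant, and no single difference was called.

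Single genes of fat and sugar metabolism changed on phenobarbital in both genotypes. FASN1 changed by -1.90 in wild type and by -1.82 in the mutant, the lipase gene bmm by 0.98 and 1.25, and Pepck1 by 3.35 and 3.64. Lower food intake on phenobarbital could produce such changes, and its test was the fasting list, which gave a camera adjusted p of 0.22 in wild type and 0.26 in the mutant. The stated prediction for its absence was wrong, because the list holds members that rise on fasting beside sug and daw, which fall. The explanation thus stayed undecided. Of the fasting list, Pepck1, bmm and tobi rose and sug and daw fell in both genotypes. AkhR fell in the mutant only, and Akh, InR, Lip4, Lst8, Pepck2, foxo and upd2 were called in neither genotype.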
